A study of Homo sapiens with 6 samples.

How the data were processed

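Gene expression was measured in SUM159 cells carrying an empty retroviral vector (control, 3 samples) or the same vector with miR-203 (miR-203, 3 samples). Groups and replicate numbers were taken from the sample titles. Per the labels, total RNA was labelled with biotin by the standard Affymetrix protocol. Per the labels, the deposited values are MAS5 intensities, 1 signal per probe set and array on a linear scale; the version of MAS5, its settings and any detection calls are not given in the sources used here. The deposited intensity values were checked for scaling: after leaving out 2% of the probe sets at each end, the mean signal was 500.1 on each array, so each array had been scaled to 1 common value. All 6 columns were matched to samples.

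Non-control probe sets (54613 of 54675) were named from the platform annotation, which can be old. A single gene was named by 41091 probe sets, several genes by 1801 and none by 11721. For 41037 of the single-gene probe sets the current symbol was taken, by Entrez identifier, from the RefSeq gene table of assembly GRCh38.p14. Single-gene probe sets named 19777 different genes; 1 list symbol was matched through a synonym. Probe sets naming several genes or none were left out of the gene tests. Signals were transformed as log2(signal + 16), so that fold changes understate the change of genes with low signal. Probe sets whose mean over the 6 arrays was below the median of all non-control probe sets (a log2 value of 6.28) were left out, which kept 27307. Each gene was represented by its single-gene probe set with the highest mean over all arrays, which left 12679 genes. Of 1062 changed genes with more than 1 probe set past the filter, 722 had all probe sets in the same direction.

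Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, two-sided, with no replicate block), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Errors of log2 changes are the moderated fit's standard errors, and errors of signals are SDs over 3 arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The fit was tested on simulated data made from the means and residual SDs of the 12679 genes, with 200 genes changed: of 50 genes each changed by 1.5, 2, 3 and 4-fold it recovered 50%, 62%, 88% and 88%, called 11 unchanged genes, and called 0 genes when no change was simulated. In simulated data the NF-kappaB and cytokine list, shifted upward, passed camera (adjusted p = 5.9e-30), and 0 other lists did. Each gene was drawn independently there, so the simulation could not show how camera behaves with correlated list members.

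The test, the samples, the filter, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. XIST was barred from the genes named by size of change, an exclusion that the fixed rule did not state. Named were the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose arrays separated by group; up to 4 members of each of 25 gene lists past the threshold, by size of change; and, whether or not they changed, SNAI2, SNAI1, ZEB1, ZEB2, TWIST1, BMI1, CDH1, VIM, CD44, LASP1, CAV1 and ABL1. The list of published miR-203 targets was drawn from general knowledge of the literature, and the other lists cover EMT transcription factors; mesenchymal, epithelial, basal, luminal, stem cell, immune, and endothelial and adipocyte markers; S phase, G2 and mitosis, TGF-beta, Wnt, NF-kappaB and cytokine, type I interferon, p53, unfolded protein and ATF4, cholesterol synthesis, hypoxia, actin and focal adhesion, keratinocyte differentiation, ribosomal, respiratory chain, microRNA machinery and housekeeping genes. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 25 lists, and with an estimated correlation. They were also tested with fry, whose p tests whether the genes of a list move, on balance, one way and whose mixed p tests for change in either direction; neither compares the list with other genes.

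Alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no filter, a stricter filter on low signals that left 7967 genes, eBayes without a trend or with robust estimation, the replicate number as a block, the mean of all probe sets of a gene, the exclusion of probe sets named _x_at or _s_at, all probe sets tested singly, a minimum of 2-fold, a threshold of 0.1, limma's treat against 1.2-fold, and leaving out each array in turn. A fit without control 2 and miR-203 3, whose residuals correlated most and whose median signals were lowest, and a fit with the log2 actin ratio as a covariate were added after the data were seen. A planned comparison of genes with and without seed sites for miR-203 in their 3-prime untranslated regions was not run, because no transcript sequences were used here, and genes named through such sites were not chosen. Neighbouring genes were ordered along the RefSeq gene table. Random lists, 10000 per gene list, were matched on mean signal in 20 bins.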

Results

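SUM159 is an established human breast cancer line of the claudin-low subtype, whose tumours have mesenchymal features and little of the claudins that seal epithelial junctions. Cells had received the retroviral vector pBabe puro, either empty (control) or carrying the microRNA miR-203 (miR-203), and had been selected with puromycin. Total RNA of 3 control and 3 miR-203 samples was hybridised to Affymetrix expression arrays of 54675 probe sets, 62 of them controls. The values were linear MAS5 signals. The median signal per array ranged from 58.2 to 77.1, and the trimmed mean was 500.1 on each of the 6 arrays. Pearson correlations of log2 signals across probe sets, which are not independent replicates, were 0.982 to 0.986 between arrays of 1 group and 0.972 to 0.979 between groups. The labels do not say whether the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical, and the number of arrays limits the precision. The level of miR-203 itself was not analysed here.

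The comparison of miR-203 with control cells asks which transcripts differ when this microRNA, known from stratified epithelia, is expressed in a claudin-low line. The actin-binding LIM protein LASP1, a published miR-203 target, fell from a signal of 7320.5 ± 456 in control to 2487 ± 197 in miR-203 cells (SD, n = 3 each). The transcription factor SNAI2 (Slug), which represses epithelial genes, fell from 2508 ± 176 to 1689 ± 118, a log2 change of -0.57 ± 0.09 (SE). The cytokine IL6 rose from 1878 ± 131 to 7215 ± 1281, and 14 of 22 tested NF-kappaB and cytokine genes rose while 0 fell. That list passed camera with the preset correlation (adjusted p = 4.7e-10) and fry (adjusted p = 0.0027), which does not compare it with other genes. It did not pass with a correlation estimated from the arrays (camera adjusted p = 0.127), a form with little power on so few arrays. Its median log2 change was 0.51 to 0.73 over the alternatives. Without control 2 and miR-203 3, 8 of its 22 genes rose, in a fit where 925 genes passed against 1880. The mesenchymal regulators ZEB1, ZEB2 and TWIST1 and the intermediate filament gene VIM (vimentin) had log2 changes between -0.01 and 0.09 that did not pass the test.

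Of 12679 genes tested with limma, 1880 (14.8%) changed at an adjusted p under 0.05, with 877 higher and 1003 lower in miR-203 cells. The median absolute change of these genes was 0.49 on the log2 scale, 1231 of them changed by under 1.5-fold, and 159 changed by at least 2-fold, with 73 higher and 86 lower. In 1873 of the 1880 genes all 3 arrays of one group lay above all 3 of the other, which held for 32.6% of all tested genes where chance gives 10%. The count was 997 without control 1, 1244 without control 3, 1032 without the mean-variance trend, and 925 without control 2 together with miR-203 3, a setting chosen after the data were seen. With each array centred on its median, 1167 genes were higher and 738 lower (38.7% lower, against 53.4% in the deposited scaling). The ratio of 5-prime to 3-prime actin signal, a measure of RNA integrity, was 0.605 ± 0.119 in control and 0.576 ± 0.238 in miR-203 samples and lowest, at 0.303, on miR-203 1. The same ratio for GAPDH was 1.05 ± 0.0234 in control and 1.05 ± 0.0222 in miR-203 samples, and 1.07 on miR-203 1. Control probe sets for the large ribosomal RNA were higher on all 3 miR-203 arrays, the middle one at 6311 ± 2008 against 2317 ± 416. Those for the small (18S) ribosomal RNA pointed the other way and did not pass. The 5-prime one was 2177 ± 327 against 3520.15 ± 2263, a difference that came from control 2 (6126, against 2380 and 2054 on controls 1 and 3). The 3-prime one, at 1234 ± 48.2 against 1500 ± 218, was lower on all 3 miR-203 arrays.

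**Figure D1:**
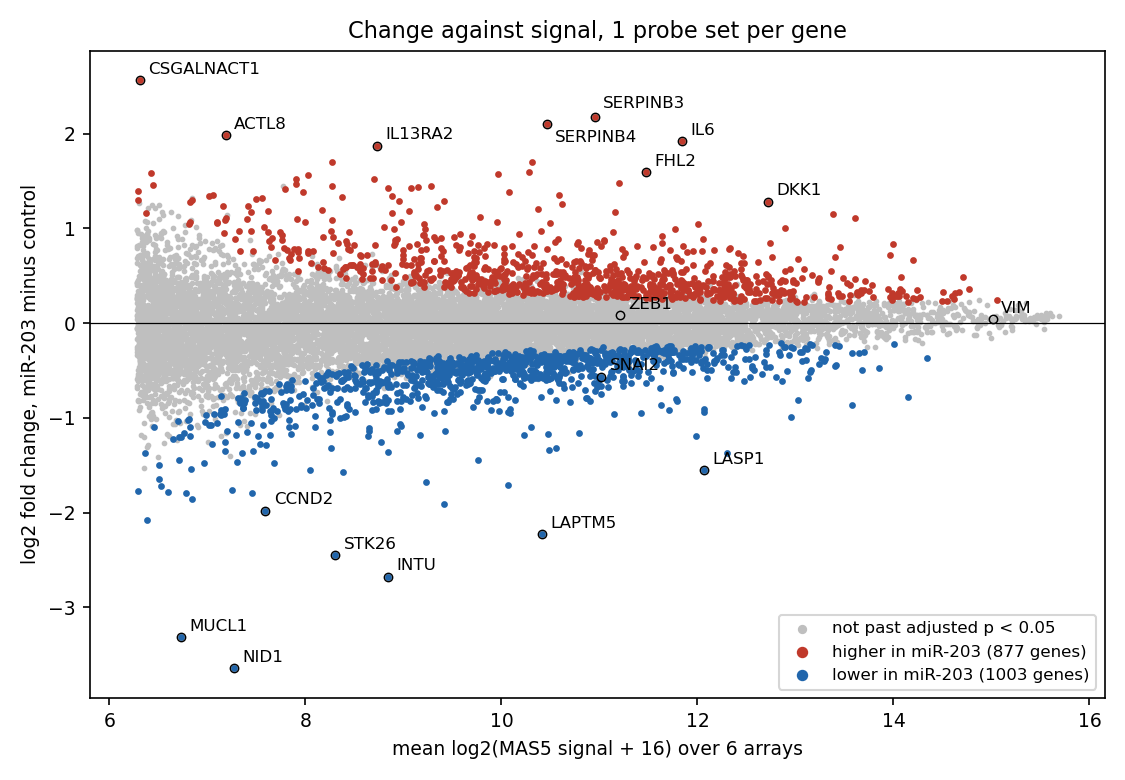
Each point is 1 of the 12679 tested genes, with the mean log2(MAS5 signal + 16) over 6 arrays on the horizontal axis and the log2 fold change, miR-203 minus control, on the vertical axis; red marks the 877 genes higher and blue the 1003 genes lower at an adjusted p under 0.05. NID1 and MUCL1 lie lowest, CSGALNACT1 lies highest, and VIM lies near 0 at high signal.

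Among the 12 genes with the largest rises, CSGALNACT1, an enzyme of chondroitin sulfate synthesis, went from 17.7 ± 9.38 to 177 ± 8.94 (log2 change 2.56 ± 0.38). Its control signal lay near the pseudocount of 16, so that the fold on this scale understates the difference. The squamous protease inhibitors SERPINB3 (2.18 ± 0.08) and SERPINB4 (2.10 ± 0.10) also rose. They are near-identical in sequence, and their probe sets may read both, so which of the pair changed is uncertain. IL6 rose by 1.92 ± 0.12 (limma adjusted p = 1.5e-06). ACTL8, an actin-like gene, rose by 1.98 ± 0.25, the interleukin-13 decoy receptor IL13RA2 by 1.87 ± 0.14, the EGF receptor ligand EREG by 1.70 ± 0.12 and the integrin subunit ITGB8 by 1.70 ± 0.15. KYNU, an enzyme of tryptophan catabolism, rose from 699 ± 66.3 to 2154 ± 268, the LIM-domain gene FHL2 by 1.59 ± 0.07 and the secreted Wnt inhibitor SOST by 1.57 ± 0.13. DCLK2 (1.58 ± 0.49, adjusted p = 0.0498) lost its call in 10 of the 15 alternative settings that gave it a value, with a log2 change of 1.04 without control 3. The other 11 passed in each setting that gave them a value. SERPINB3, SERPINB4 and FHL2 had none without probe sets named _x_at or _s_at. ACTL8 and ITGB8 had none under a stricter filter on low signals, and CSGALNACT1 had a value in 13 of the 19 settings.

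Of the 12 genes with the largest falls, the basement membrane glycoprotein gene NID1 fell from 529 ± 2.39 to 35.7 ± 29.6 (log2 change -3.64 ± 0.44, adjusted p = 0.00025); the other NID1 probe set past the filter had a log2 change of -0.81 (adjusted p = 0.150), and the mean of both gave -2.23, a smaller fall than that of MUCL1 or INTU. MUCL1, a mucin-like gene of breast epithelium, went from 319.8 ± 45.4 to 18.7 ± 11.04 (-3.32 ± 0.33). Its signal in miR-203 cells lay near the pseudocount, and its log2 change ranged from -4.19 to -2.22 over the alternatives. INTU, needed for assembly of cilia, fell by 2.68 on the log2 scale, from 1144 ± 36.1 to 166 ± 20.1. The kinase gene STK26 fell by 2.45 and LAPTM5, which encodes a lysosomal membrane protein of blood cells, fell by 2.22, from 2928 ± 45.4 to 622 ± 121. CCND2 (cyclin D2) fell by 1.98; a second probe set of CCND2 gave -0.58 (adjusted p = 0.420), and the mean of its probe sets -1.28. The other members of the 12 were SH3YL1 (-1.91 ± 0.14), the secreted protein genes CRISP3 (-1.86 ± 0.28) and OLFML3 (-1.79 ± 0.26), the Rag GTPase gene RRAGD (-2.08 ± 0.45), the acyl-CoA dehydrogenase gene ACADL (-1.79 ± 0.45) and C3orf18 (-1.78 ± 0.42). The calls of RRAGD, C3orf18 and ACADL were lost in 1, 2 and 5 of the 14, 17 and 17 settings that gave them a value. Their mean signals in miR-203 cells were low (29.5, 43.0 and 53.4). Over the alternatives their log2 changes ranged from -2.55 to -1.28, from -2.25 to -1.14 and from -2.27 to -1.18.

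Gene lists fixed before the data were examined were then compared. Of 25 lists, 9 passed limma's camera test at an adjusted p under 0.05, each in the direction of miR-203. None passed with a correlation estimated from the arrays (limma, 6 at an unadjusted p under 0.05), while 9 lists passed fry, 6 of them shared with camera. With an estimated correlation camera rests on the few residual degrees of freedom of the 6 arrays and has little power. The lists of G2 and mitosis, actin and focal adhesion, and unfolded protein and ATF4 genes passed camera and not fry, and those of p53 targets (up), respiratory chain genes (down) and immune markers (down) passed fry and not camera. Members beyond the 4 with the largest change per list are named only to complete small counts and were chosen after their values were seen.

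Published miR-203 targets, 27 tested, did not move in 1 direction as a list (camera adjusted p = 0.972). Over all genes 5 fell and 3 rose, and 5 fell and 5 rose adjusted over the list alone. Among all 12679 tested genes 1003 fell and 877 rose. The fry mixed p, for change in either direction, was 1.5e-06, but that test does not compare the list with other genes. LASP1 fell by 1.55 on the log2 scale (SE 0.08, limma adjusted p = 6.0e-07), and SNAI2, ZNF281 (-0.51 ± 0.08), ATM (-0.50 ± 0.10) and PRKCA (-0.47 ± 0.09) also fell. The Wnt inhibitor DKK1 rose from 4301 ± 42.6 to 10507 ± 998 (1.28 ± 0.08), and ASAP1 (0.41 ± 0.09) and SMAD1 (0.37 ± 0.08) rose. The targets ABL1 (0.25 ± 0.09, adjusted p = 0.0878) and CAV1 (0.24 ± 0.10, adjusted p = 0.119) did not pass. ABL1 passed without miR-203 1, after median centring and with the actin covariate, and its adjusted p ranged from 0.0386 to 0.438 over the alternatives. CAV1 passed without miR-203 2 (0.34) and was 0.13 without miR-203 1, with adjusted p between 0.0338 and 0.334. With each array centred on its median 5 targets rose, and without a mean-variance trend 1 rose. Without control 2 and miR-203 3, 3 fell. BMI1 was not analysed here.

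Of 13 tested EMT transcription factors, SNAI2 fell (limma adjusted p = 0.0015), FOXQ1 (0.43 ± 0.08) and HMGA2 (1.07 ± 0.27, lost in 5 of 17 settings) rose, and the counts adjusted over the list alone were the same 2 and 1 (camera adjusted p = 0.217). ZEB1 had signals of 2286 ± 96.0 and 2427 ± 47.6 in control and miR-203 cells, ZEB2 of 553 ± 66.1 and 552 ± 101, and TWIST1 of 359 ± 29.3 and 376 ± 60.7. SNAI1 lay below the filter on low signals, at 63.6 ± 13.3 and 53.2 ± 13.8. So did both probe sets of the epithelial cadherin CDH1, with mean signals of 5.18 to 19.3.

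**Figure D2:**
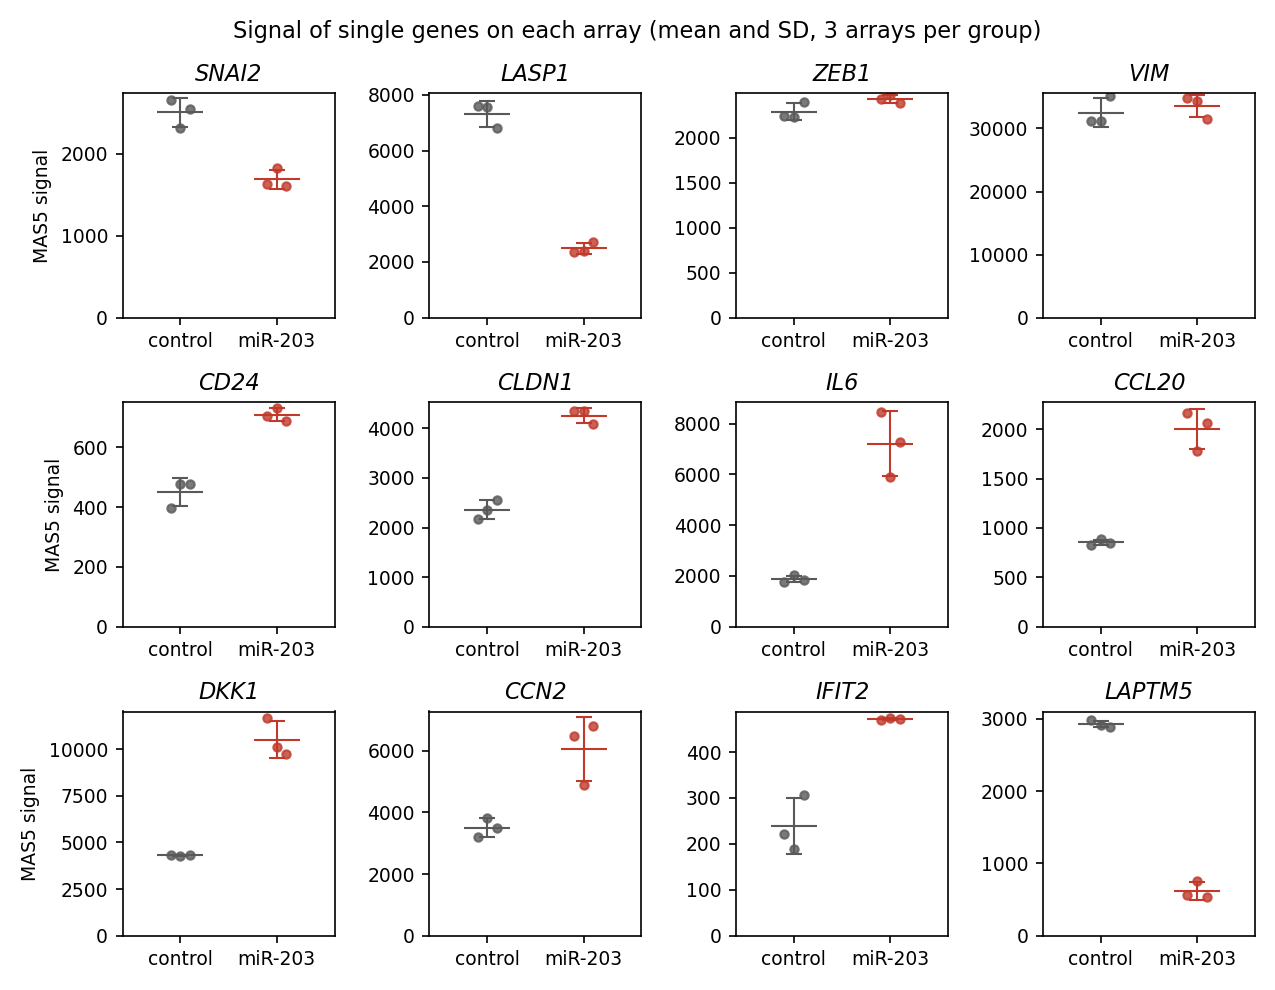
Points are the linear MAS5 signals of 12 genes on each array (grey, 3 control; red, 3 miR-203), with bars for the mean and SD and the vertical axis starting at 0. SNAI2, LASP1 and LAPTM5 were lower on all 3 miR-203 arrays, ZEB1 and VIM overlapped between groups, and the other 7 genes were higher.

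Of 27 mesenchymal markers, 9 rose and 1 fell (11 and 1 adjusted over the list alone), and the list passed camera (adjusted p = 0.0072; adjusted p = 0.164 with an estimated correlation). The collagen gene COL3A1 (1.24 ± 0.27), the cadherin gene CDH11 (1.10 ± 0.18), TAGLN (0.80 ± 0.11) and S100A4 (0.79 ± 0.09) rose, and the collagen gene COL5A1 (-0.53 ± 0.08) fell. VIM was 32526 ± 2307 in control and 33554 ± 1740 in miR-203 cells. Under quantile normalization 9 mesenchymal markers rose and 3 fell. The second CDH11 probe set gave -0.19 (adjusted p = 0.820). TAGLN was 0.13 without _x_at and _s_at probe sets and did not pass there, nor did CDH11 with the mean of probe sets (0.46) or COL3A1 without control 2 and miR-203 3. Without probe sets that can match several transcripts (names ending in _x_at or _s_at), 1 of 16 mesenchymal markers rose and the list did not pass (adjusted p = 0.367). It also missed the threshold under a stricter filter on low signals (adjusted p = 0.0542), and its median log2 change of 0.06 was 0.16 without miR-203 1.

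Of 18 tested epithelial markers, the tight junction gene CLDN1 (0.85 ± 0.08) and the keratin gene KRT18 (0.40 ± 0.06) rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0557, highest and lowest across settings 0.563 and 0.0145). The epithelial list passed without control 3, without miR-203 1 and without miR-203 3, and also under quantile normalization, the stricter filter and the mean of probe sets, and with the actin covariate. Of 10 basal mammary markers, the laminin subunit gene LAMB3 (1.52 ± 0.16) and the integrin subunit gene ITGA6 (0.42 ± 0.11, lost in 8 of the 19 settings) rose, 3 adjusted over the list alone, and the list passed camera (adjusted p = 0.0072; adjusted p = 0.164 with an estimated correlation; the median of 0.34 was 0.21 without miR-203 2). Of 10 luminal markers, KRT18 rose and SPDEF (-0.80 ± 0.25, adjusted p = 0.0491) fell, 2 and 1 adjusted over the list alone (camera adjusted p = 0.480). The SPDEF call was lost in 13 of 17 settings, and 2 of the gene's 4 probe sets pointed the other way. The luminal list had a median of 0.05 and a mean of -0.05, and camera's direction was up.

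Among 14 breast stem cell markers, CD24 (0.64 ± 0.12, higher in 6 of 6 probe sets), KLF4 (0.55 ± 0.09) and ITGA6 (lost in 8 of the 19 settings) rose. SNAI2 and PROCR (-0.32 ± 0.08) fell, and 4 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.328). Without _x_at and _s_at probe sets, 1 of 8 members rose and 2 fell. CD44 was 7163 ± 618 in control and 8296 ± 508 in miR-203 cells, which did not pass over all genes (limma adjusted p = 0.101). Of its 9 probe sets 8 were higher in miR-203 cells. Probe sets of lower signal gave 0.36 (limma adjusted p = 0.0151 over all probe sets) and 0.57 (0.0289), and the others did not pass.

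NF-kappaB and cytokine genes moved most as a list. Over all genes 14 of 22 rose and 0 fell (15 and 0 adjusted over the list alone), with a median log2 change of 0.62 (camera adjusted p = 4.7e-10; adjusted p = 0.127 with an estimated correlation). IL1A rose from 331 ± 38.9 to 935 ± 201 (1.44 ± 0.16, limma adjusted p = 0.00016), the chemokine gene CCL20 from 854 ± 26.9 to 2002 ± 200.1, and the adaptor gene TRAF1 from 76.7 ± 49.0 to 191 ± 21.6 (1.34 ± 0.41, adjusted p = 0.0445, lost in 9 of 18 settings and 0.79 without control 3). Without control 2 and miR-203 3, 8 of 22 members rose, and without the _x_at and _s_at probe sets 8 of 15.

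Of 28 type I interferon response genes 8 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.00027; adjusted p = 0.164 with an estimated correlation). EPSTI1 (1.35 ± 0.14), the interferon-induced genes IFIT2 (0.96 ± 0.17) and IFIT3 (0.93 ± 0.15) and the transcription factor IRF7 (0.89 ± 0.26, lost in 8 of 17 settings) rose, and PARP9 (-0.65 ± 0.13) fell. The second IFIT3 probe set gave 0.16 (adjusted p = 0.706), and the mean of both 0.54. Without control 3, or without miR-203 2, 5 members rose. Of 23 TGF-beta response genes 9 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 0.00027; adjusted p = 0.127 with an estimated correlation). The matrix-associated gene CCN2 rose from 3511 ± 299 to 6059.8 ± 1026, PMEPA1 by 0.75 ± 0.13, and the basement membrane collagen genes COL4A2 (0.87 ± 0.19) and COL4A1 (0.79 ± 0.18) rose, while ID2 (-0.66 ± 0.11) fell. The calls of COL4A2 and COL4A1 were lost in 2 and 1 of 18 settings, COL4A1 without miR-203 1. The other COL4A2 probe set gave -0.18 (adjusted p = 0.845), and with the mean of probe sets COL4A2 was 0.35 and did not pass, while PMEPA1 was 0.43. In the list, 4 members rose without control 2 and miR-203 3.

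Actin and focal adhesion genes, 30 tested, passed camera with 8 rising and 1, LASP1, falling (10 and 1 adjusted over the list alone; adjusted p = 8.7e-05; adjusted p = 0.346 with an estimated correlation). The calponin gene CNN3 (0.73 ± 0.09), the integrin subunit gene ITGA2 (0.73 ± 0.11) and the caveolin gene CAV2 (0.61 ± 0.08, lost without _x_at and _s_at probe sets) rose. Without control 1, 5 members rose.

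**Figure D3:**
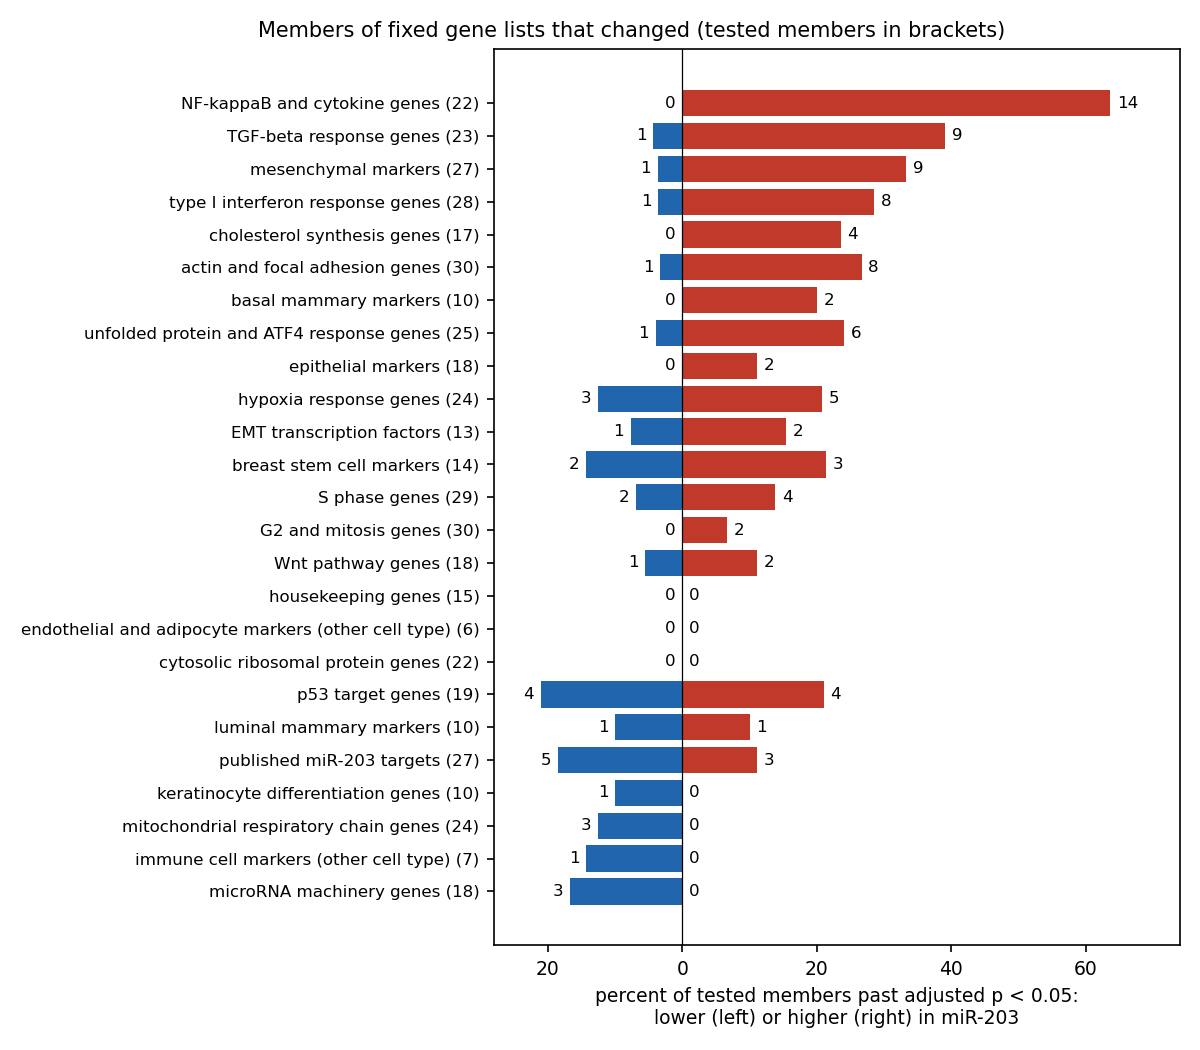
Bars give the percent of tested members of each of the 25 fixed lists past a limma adjusted p under 0.05, lower in miR-203 cells to the left (blue) and higher to the right (red), with the number of genes at the bar end and the number tested in brackets. The NF-kappaB and cytokine list has the longest bar, 14 of 22 tested genes.

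Of 30 G2 and mitosis genes ANLN (0.46 ± 0.10) and CCNB1 (0.26 ± 0.08) rose and 0 fell, 1 and 0 adjusted over the list alone. The list passed camera (adjusted p = 0.0047; adjusted p = 0.423 with an estimated correlation), with a median of 0.15 that was 0.08 without miR-203 1. The CCNB1 call was lost in 12 of the 19 settings and that of ANLN in 1, and 6 members rose after median centring. Of 29 S phase genes RRM2 (0.89 ± 0.11), CDC45 (0.83 ± 0.12), TYMS (0.33 ± 0.10) and RRM1 (0.31 ± 0.08) rose, and CCNE1 (-0.40 ± 0.12) and RFC4 (-0.38 ± 0.09) fell, 6 and 4 adjusted over the list alone (camera adjusted p = 0.328). The calls of CCNE1 and RFC4 were lost in 14 and 5 of the 19 settings, and 2 members rose without control 1, without control 3, without miR-203 1 or without miR-203 3.

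Of 25 unfolded protein and ATF4 response genes 6 rose and 1, the lipoprotein receptor gene VLDLR (-0.67 ± 0.19), fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.01001; adjusted p = 0.443 with an estimated correlation). CRELD2 (0.87 ± 0.16), the stress transcription factor gene ATF3 (0.69 ± 0.09) and the chaperone gene HSP90B1 (0.64 ± 0.11) rose. The list missed the threshold under quantile normalization (adjusted p = 0.0927, with a median log2 change of 0.10 against 0.17), without control 1 (adjusted p = 0.0510, with 3 members rising), without miR-203 3 (adjusted p = 0.0849), without control 2 and miR-203 3 (adjusted p = 0.103) and with fry (adjusted p = 0.0875). Its adjusted p ranged from 0.00056 to 0.443 over the alternatives. Calls were lost in 10 of 17 settings for VLDLR and in 1 each for CRELD2, ATF3 and HSP90B1. Of 17 cholesterol synthesis genes DHCR7 (0.94 ± 0.10), FDPS (0.71 ± 0.09), MSMO1 (0.36 ± 0.10) and LSS (0.35 ± 0.08) rose and 0 fell, the same 4 and 0 adjusted over the list alone (camera adjusted p = 0.01001; adjusted p = 0.164 with an estimated correlation). The other LSS probe set gave -0.24 and did not pass. The calls of MSMO1 and LSS were lost in 6 and 5 of the 19 settings, and 2 members rose without control 1 or without control 2.

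Of 19 p53 target genes CDKN1A (0.89 ± 0.13), TP53I3 (0.79 ± 0.10), MDM2 (0.66 ± 0.15, lost in 4 of the 19 settings) and TNFRSF10B (0.35 ± 0.08) rose, and ZMAT3 (-0.90 ± 0.11), PHLDA3 (-0.59 ± 0.15), XPC (-0.47 ± 0.12) and CCNG1 (-0.25 ± 0.07) fell, 8 and 4 adjusted over the list alone (camera adjusted p = 0.143). After median centring 8 rose and 3 fell, and without control 1, control 2 or miR-203 3, 1, 1 and 2 members fell. Of 24 hypoxia response genes PFKFB4 (0.97 ± 0.23), ADM (0.85 ± 0.09), HK2 (0.79 ± 0.08), SLC2A1 (0.41 ± 0.08) and EGLN1 (0.32 ± 0.08) rose, and MXI1 (-0.50 ± 0.15), P4HA2 (-0.37 ± 0.10) and BNIP3L (-0.29 ± 0.08) fell, 6 and 3 adjusted over the list alone (camera adjusted p = 0.143; 0.0456 without miR-203 2, and 0.0456 to 0.571 over the alternatives). The other 2 HK2 probe sets gave -0.10 and -0.24 and did not pass, and with the mean of probe sets HK2 was 0.15 (limma adjusted p = 0.493). Without control 2 and miR-203 3, the PFKFB4 call was lost and 2 hypoxia members rose. The MXI1 call was lost in 10 of the 19 settings. After median centring and without control 1, control 2, control 3, miR-203 2 or miR-203 3, 0 or 1 members fell. Of 18 Wnt pathway genes DKK1 and RNF43 (0.55 ± 0.17, lost in 10 of 18 settings) rose and DKK3 (-0.38 ± 0.07) fell, the same counts adjusted over the list alone (camera adjusted p = 0.497). The DKK3 probe set outside the _x_at and _s_at classes gave 0.24, which did not pass.

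No member of 22 cytosolic ribosomal protein genes (camera adjusted p = 0.217), 15 housekeeping genes (0.198) or 6 endothelial and adipocyte markers (0.480) passed, either over all genes or adjusted over the list alone (limma; at an unadjusted p under 0.05 they held 0, 3 and 1 members). The ribosomal list passed camera, upward, without control 3 (adjusted p = 0.0011) and without miR-203 3 (0.0220), and the housekeeping list without control 3 (0.0321). Over the alternatives their adjusted p ranged from 0.0011 to 0.849 and from 0.0321 to 0.979. Among 24 mitochondrial respiratory chain genes UQCRC2 (-0.44 ± 0.07), NDUFB5 (-0.40 ± 0.07) and SDHD (-0.31 ± 0.09, lost in 10 of the 19 settings) fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 0.143, passing, downward, under quantile normalization, where 5 fell, and with the mean of probe sets). Among 18 microRNA machinery genes the GW182-family gene TNRC6B (-1.03 ± 0.22) and the RNA helicase genes DDX5 (-0.64 ± 0.15) and DDX17 (-0.30 ± 0.08) fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 0.972). That list had a median of 0.01 and a mean of -0.06, camera's direction was down, and 1 member fell without control 1 or without control 3. The calls of TNRC6B, DDX5 and DDX17 were lost in 2 of 18, 3 of 19 and 11 of 19 settings, that of NDUFB5 without control 2 and miR-203 3. With the mean of probe sets TNRC6B was -0.60, and 1 of 4 DDX17 probe sets pointed the other way (0.29). Among 10 keratinocyte differentiation genes CSTA (-0.57 ± 0.12) fell and 0 rose (camera adjusted p = 0.972), and among 7 immune cell markers LAPTM5 fell and 0 rose (camera adjusted p = 0.217), both with the same counts adjusted over the list alone. The CSTA call was lost without a mean-variance trend.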

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

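The comparison of the real grouping with other splits was chosen only after the result was seen, and so was the covariate fit as an alternative setting.

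Control probe sets were left out of the gene tests. In a limma fit over all probe sets of the array, those for the large ribosomal RNA, AFFX-M27830_5_at and AFFX-M27830_M_at, had log2 changes of 0.70 ± 0.16 (adjusted p = 0.0475) and 1.41 ± 0.19 (adjusted p = 0.0035) in miR-203 against control and were higher on all 3 miR-203 arrays. Of the 62 control probe sets, these 2 passed, and the arrays of 14 separated by group, 4 higher and 10 lower, where chance gives 10%. Of the 10 lower ones, 9 were for bacterial transcripts added as controls, none past the test, and 1 for the small ribosomal RNA. Of 4227 probe sets past the filter that name no gene or several genes, 241 passed the limma test over all 27307 probe sets past the filter, 101 higher and 140 lower.

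For the 1880 genes that changed, degraded RNA in part of the arrays stays open: with the actin ratio as a covariate their median change kept 99.6% of its size, but the ratio differed between groups by less than its spread, so the covariate had little group difference to remove. Without miR-203 1, whose actin ratio was lowest, 1744 genes passed, 1484 of them shared, and the GAPDH ratio, 1.05 in both groups, was 1.07 on that array. These values argue against low RNA integrity of miR-203 1 as the source of most of the calls. They do not address a difference shared by all 3 miR-203 arrays. The large ribosomal RNA controls, higher on all 3, were not tried as a covariate. A copy number difference between the cell populations stays open: along the gene order, 218 pairs of neighbours were called in the same direction, 1.56 times the mean of 139 in shuffles (95% of shuffles between 118 and 161), a ratio between the bounds of 1.5 and 2 set for it, and the largest absolute median log2 change of 25 neighbours was 0.45, above the central 95% of shuffles, which ended at 0.37. Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many genes, the real one with 1880. The highest of the other splits gave 0 (limma, 155 to 550 at an unadjusted p under 0.05). Each of those mixes arrays of both groups, so a group difference would raise its spread and lower its count. The 10 splits are also too few for a share under 0.05. An effect of miR-203 itself is the difference the design names, and it could not be separated from differences that arose between the populations during infection and selection.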

How the results depend on the processing

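The fits without control 2 and miR-203 3 and with the actin covariate were chosen only after the result was seen. For genes changed, miR-203 against control, the count was 1880. It was 1916 under quantile normalization, 1905 under median centring, 1854 and 1915 with pseudocounts of 1 and 64, 1481 without a filter, 1782 under a stricter filter, 1893 with robust eBayes, 1449 with the mean of probe sets, 1371 without _x_at and _s_at probe sets, 2473 over all probe sets, 2662 at a threshold of 0.1 and 2043 with the covariate. It was 1032 without a trend (962 shared; the cause was not tested), 159 with a 2-fold minimum and 292 with treat, which both ask for a larger change by construction, and 925 without control 2 and miR-203 3 (871 shared), which uses fewer samples. Leaving out 1 array, which also means fewer samples, gave 997 (without control 1) to 1744, and 1244 without control 3. With the replicate number as a block 1408 genes passed, 1374 of them shared, but the numbers did not pair the samples: deviations from the group means correlated at 0.10, -0.11 and -0.16 across genes, which are not independent, for numbers 1, 2 and 3. Of the fixed gene lists 9 passed camera, 8 to 12 when 1 array was left out, and 8 to 11 in the other refits, and 9 passed fry. With an estimated correlation 0 passed (limma, 6 at an unadjusted p under 0.05). That form of camera refers its statistic to the few residual degrees of freedom of the 6 arrays. With a preset correlation it uses the number of genes, so the estimated form has far less power. For the TGF-beta, mesenchymal and cholesterol synthesis lists the estimate (-0.0005, -0.02 and -0.03) lay below the preset 0.01. A higher correlation therefore cannot account for their loss. For the other lists that passed camera the estimate was higher, from 0.016 to 0.205. There the correlation and the lost degrees of freedom were not told apart.

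For 93 named genes under 19 alternatives, 1517 values had the same direction and side of the threshold, 180 lost the call, 4 gained it and 1 reversed. DKK3, at -0.38, was 0.24 (adjusted p = 0.213, over the alternatives 0.00088 to 0.213) without _x_at and _s_at probe sets, where another probe set stands for the gene. Another 65 values were missing, because the filter or the choice of probe sets left the gene untested. Of 45 called named genes with a value under all 19 alternatives, 25 were called in each; of all 86 called named genes, 49 were called wherever they had a value. Without control 1, 2 and 3, 16, 15 and 12 of these calls were lost, without miR-203 1, 2 and 3, 8, 11 and 13, without a trend 21, and without control 2 and miR-203 3, 23. The 25 lists gave 486 values on the same side, 18 weaker, 16 stronger and 0 reversed. The seed-site comparison and its alternatives were not run. Signals near the pseudocount limit the folds: for NID1, log2 fold change was -4.77 and -2.62 with pseudocounts of 1 and 64.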

Other observations

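The family scan, the comparison of the published targets with random lists, the immune marker test and the fit without control 2 and miR-203 3 were tests chosen only after the result was seen.

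Genes were grouped into families by the letters of the symbol before its first digit, and 195 families of at least 8 tested genes were compared with limma's camera; the families and members named here were chosen after their values were seen. Of 8 CXCL chemokine genes, 6 rose and 0 fell (median log2 change 0.86, camera adjusted p = 0.00017, adjusted p = 0.967 with an estimated correlation). The estimated form rests on the few residual degrees of freedom of the 6 arrays, so over 195 families it could hardly pass any. Its value of 0.967, here and for the IFT and ZNF families below, therefore decides little. CXCL1, CXCL2 and CXCL8 are also in the NF-kappaB and cytokine list, as is CXCL3 (0.53 ± 0.18), which did not pass. Outside that list, CXCL12 rose from 162 ± 28.6 to 356 ± 55.1 (1.06 ± 0.19), CXCL10 by 0.96 ± 0.21 and CXCL11 by 0.95 ± 0.24. All 8 changes were positive, and the central 95% of medians of 10000 random lists matched on signal ran from -0.29 to 0.20. Only the CXCL, ZNF and IFT families, with the smallest camera p of the 195, were set against random lists. Their place outside those ranges follows in part from that choice and adds no separate evidence. The family median was 0.52 to 0.96 across the settings, 4 members rose without control 3 or without miR-203 3, and 2 rose without control 2 and miR-203 3.

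Of 18 IFT genes, which encode intraflagellar transport proteins that carry cargo along cilia, 8 fell, 0 rose and 17 had negative log2 changes (median -0.33; camera adjusted p = 0.0014; adjusted p = 0.967 with an estimated correlation; random lists -0.18 to 0.13). IFT70B (-0.97 ± 0.27), IFT74 (-0.51 ± 0.11), IFT88 (-0.49 ± 0.15) and IFT20 (-0.41 ± 0.08) fell, as did INTU, also a cilium gene. Of 21 genes of the CFAP family, also named for cilia, 2 fell and 1 rose, and that family did not pass (camera adjusted p = 0.763). The median was -0.40 to -0.28 across the settings, but the number that fell was 2 without control 1, control 3 or miR-203 3, 5 without control 2, 4 without miR-203 2, 3 after median centring and 1 without control 2 and miR-203 3. Of 350 genes with symbols beginning in ZNF, most of them zinc finger genes, 41 fell, 4 rose and 261 had negative changes (median -0.22; camera adjusted p = 0.00055; adjusted p = 0.967 with an estimated correlation; random lists -0.08 to -0.01). ZNF420 (-1.35 ± 0.22), ZNF44 (-1.14 ± 0.19), ZNF32 (-0.85 ± 0.14) and ZNF148 (-0.78 ± 0.11) fell. How many of the 218 neighbour pairs called in the same direction were ZNF genes was not tested. The fall of the family and the neighbour count may therefore share genes. The ZNF median was -0.23 to -0.15 across the settings, and 18 fell without control 1, 25 without control 2, 24 without control 3, 25 without miR-203 2 and 17 without control 2 and miR-203 3.

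Published miR-203 targets did not fall as a list. Low signal of its members was argued against, since their median standard error of 0.0903 lay below that of all tested genes, 0.127, a difference of -0.0371. A fall too small for the list test stays open: the list's median of -0.01 lay at or above that of 34.8% of 10000 random lists matched on signal, whose central 95% ran from -0.09 to 0.11. Its members went both ways, 14 down and 13 up. An effect of miR-203 on few of these messages, or on translation more than on message level, may apply and was not tested.

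The NF-kappaB and cytokine list passed camera upward with the preset correlation and not with an estimated one (adjusted p = 0.127). Scaling between arrays was argued against, since the lower of its medians under quantile normalization and median centring was 102% of that in the deposited scaling. Immune cells among the miR-203 cells have no named source in the design, which used a puromycin-selected cancer line, but the markers could not exclude them. Of 20 immune markers 7 were tested, and 0 rose past the test. Of the 7, 2 had positive log2 changes, PTPRC (0.40 ± 0.22) and CSF1R (0.32 ± 0.30). The immune list passed fry downward (adjusted p = 0.0032) and did not pass camera (adjusted p = 0.217). The most abundant, LAPTM5, fell from 2928 to 622, a marker so high in control that a small share of other cells would not show in it, while HBB was 246 in control and 199 in miR-203 cells and CD79A 198 and 181. A response of the cells to miR-203 is the difference the design names, and it stays a hypothesis beside differences that arose between the populations during infection and selection.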
